A study of Homo sapiens with 2 samples.

How the data were processed

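RNA libraries of 95D human lung cancer cells were analysed, 1 from cells kept for 48 h in medium without glucose and 1 from cells kept for 48 h without glutamine, after 24 h in complete medium. Per the labels, total RNA was taken, ribosomal RNA was depleted and sequencing was paired-end. RNA immunoprecipitation sequencing, which the series' title names, pulls down a protein and sequences the RNA bound to it; neither sample's label says that its library is such a pull-down or an input, and the description of the glutamine-deprived sample names the same table column as that of the other. The submitters' processing notes name the aligner HISAT2 2.0.5, the transcript assembler StringTie and the human genome build hg38, without the role or settings of each. The counting tool, annotation, filters and normalization are not given in the sources used here.

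Per the file headers, rows are named as long non-coding RNA gene names and the value column by condition, and no unit is stated. Each deposited file held the same transcripts in the same order, without transcript identifiers, and a mark in place of a number where no value was given; such rows were left out. A tiny positive placeholder stood where 0 was meant, and values under 1e-09 were set to 0. The deposited values are not whole-number counts. Their low values climbed in equal steps, of 1.264 in the glucose-deprived and 0.791 in the glutamine-deprived library. Apart from small fitted offsets of 0.022 and -0.018, read counts multiplied by 1 factor per library would do so, and the values were not divided by transcript length. Subtracting the offset and dividing by the step gave whole numbers within 0.1 of a read for 100% of the 472 and 18536 values up to 1000 reads. These recovered reads were used for depth, shares and intervals. How the authors chose the factors is not stated. The steps are close to reciprocals of each other, with a ratio of 1.60, while the recovered reads differed 33.7-fold. The sums of the values, 54149 and 1140830, were far from equal. This matters for every ratio between the libraries, since the deposited scale sets it. The whole-series table held the same values and was not used.

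Design choices, the gene lists and most of the other settings tried were fixed before the data were examined. The design had foreseen counts or FPKM or TPM of all genes; its branch for normalized values was used. Values of transcripts sharing a name were summed. Names at 1 or more in either library were kept, which all 9253 were, and ratios are log2(value + 1) of the glutamine-deprived minus the glucose-deprived library, which understates differences of low names. With 1 library per condition no test was run. A name at least 2-fold apart is a description of these libraries. Of the names, 6909 were symbols in the RefSeq table of assembly GRCh38.p14, 1937 were Ensembl identifiers, 358 were unnamed loci and 49 were other symbols; the table served for names and gene classes only, and no coordinates are printed because the files hold none. A name had 1 to 53 transcripts, and reads shared between overlapping transcripts, antisense partners, paralogs or pseudogenes cannot be told apart here.

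The named genes were chosen by a rule fixed beforehand: the 12 names with a symbol with the highest and the 12 with the lowest log2 ratio and a value of at least 5 in the higher library, the 10 most abundant of each library, ALKBH5, up to 4 measured members of each list with the largest absolute log2 ratio, and any member needed to name a count of 5 or fewer. A few names outside the rule are marked as chosen after their values were seen, and a few names within it are not reported here. For each of 38 lists with 883 entries the median log2 ratio was given with its order-statistic interval, from 6 measured members upward, and its percentile among 10000 random lists of the same size matched on mean level in 20 bins. The members above 0 in the glucose-deprived library were compared with random lists matched on the value in the glutamine-deprived library, a comparison added after the data were seen. Intervals of shares are 95% Wilson intervals from recovered reads or numbers of transcripts. Depth was 42827 recovered reads in the glucose-deprived and 1442572 in the glutamine-deprived library; these are the reads of the listed transcripts, and the depth of the whole libraries is not known. A name at 0 in the glucose-deprived library was given no upper limit, because the values there did not behave as a simple read count of independent molecules.

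Alternatives were rescaling to 1000000 per library, centring on the median ratio, a pseudocount of 0.1, a minimum of 5, a minimum of 1 in both libraries, no minimum, protein-coding symbols only, and thresholds of 1.5-fold and 4-fold. The calculations were tested on simulated data, a pair of libraries of near-equal depth built on 9211 glutamine-deprived names. Recovery and false calls were counted only among names above a minimum number of reads. Of these, 100% of 200 names changed 4-fold were recovered, and 1 of 2957 unchanged names was called. Among unchanged random lists, 4% fell outside the central 95%. The simulated pair lacked the unequal depth and many zeros of the real libraries, so it gives no error rate for them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.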

Results

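RNA was measured in 95D cells, a human lung cancer cell line, after 48 h without glucose or without glutamine. The labels give 2 samples, 1 per nutrient condition, so no difference below has a replicate check and no p-value is given, across genes or otherwise. The series' title and design text describe an immunoprecipitation of RNA bound to ALKBH5, an enzyme that removes the m6A mark from RNA, set against total input RNA. The labels of the individual samples do not say whether either library is an immunoprecipitate or an input. Binding to ALKBH5 over input is therefore not analysed here, and the comparison made is that of the glutamine-deprived with the glucose-deprived library. Each file listed transcripts under a heading for long non-coding RNA names, and 18663 transcripts carried a value. Many of these carry the name of a protein-coding gene. A value under such a name is that of the transcripts listed there and is not taken as the level of the gene's messenger RNA. Without transcript identifiers, whether such rows hold reads of that messenger RNA cannot be told. Values were summed over the transcripts of a name, which gave 9253 names.

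The plainest difference between the libraries was how many of the transcripts with a value stood above 0. In the glucose-deprived library 474 of these 18663 were above 0, or 2.54% (95% Wilson interval 2.32 to 2.78%). In the glutamine-deprived library 18564 were, or 99.5% (99.4 to 99.6%). Every transcript with a value was above 0 somewhere, 375 in both libraries, 99 in the glucose-deprived alone and 18189 in the glutamine-deprived alone. Rows without a value are not counted, so these percentages are not shares of the whole table. The 99.5% and its interval largely reflect which rows carried a value. MALAT1 and NEAT1, nuclear long non-coding RNAs, were above 0 in both, at 1308 and 506 in the glucose-deprived library and at 68578 and 25450 in the glutamine-deprived library. ACTB and GAPDH, used as reference genes in many assays, were listed at 0 in the glucose-deprived library and at 798 and 810.0 in the glutamine-deprived library. By name, 351 were above 0 in both libraries, 8860 in the glutamine-deprived library alone and 42 in the glucose-deprived library alone. The deposited values summed to 54149 and 1140830, a 21.1-fold difference. The whole reads behind them, recovered from the step between low values, came to 42827 and 1442572. Of the 7 measured names on the housekeeping list, PPIA was the 1 above 0 in the glucose-deprived library, at 377. Random lists matched on level held 1 (0 to 3). Because most names stood at 0 in that library, a 0 there is reported as listed at 0 and no fold is printed for a single name against it.

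**Figure D1:**
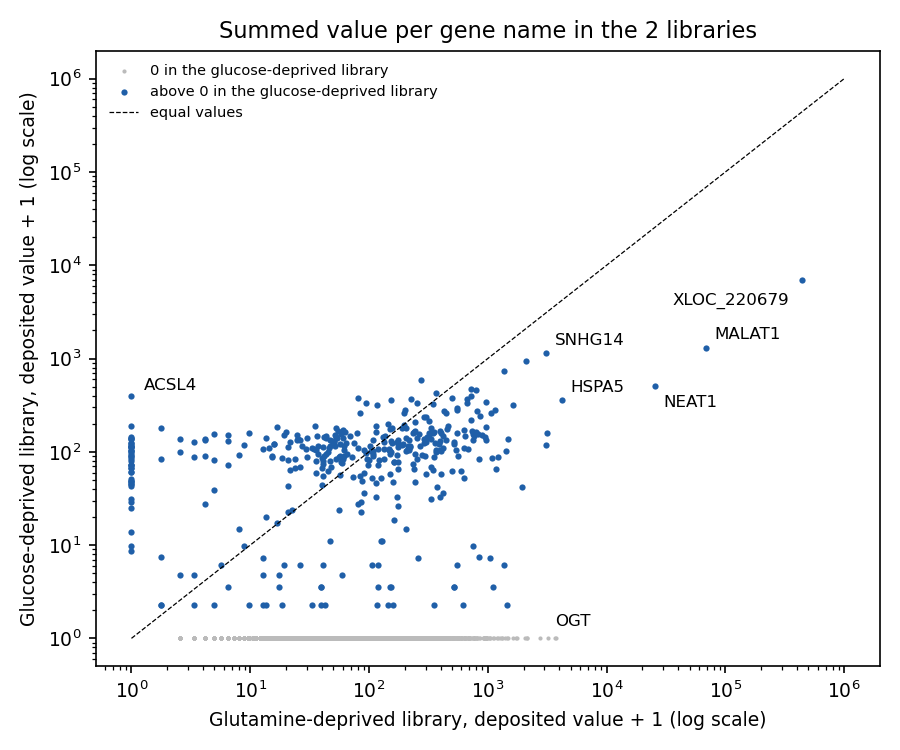
Each point is 1 of 9253 gene names, with its summed deposited value plus 1 in the glutamine-deprived library on the horizontal log axis and in the glucose-deprived library on the vertical log axis; grey points are names at 0 in the glucose-deprived library, blue points are names above 0 there, and the dashed line marks equal values. The 393 blue points mostly lie in a band near 100 on the vertical axis over a wide range of glutamine-deprived values, and XLOC_220679, MALAT1 and NEAT1 stand at the far right.

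On the deposited values, 9008 names were at least 2-fold higher in the glutamine-deprived library and 131 were at least 2-fold higher in the glucose-deprived library, on the log2(value + 1) scale. Of the 9008, 8860 were listed at 0 in the glucose-deprived library, so they count as 2-fold apart through the pseudocount and not through a measured fold. With each library rescaled to 1000000 the counts were 8881 and 347, and with log2 ratios centred on their median, which by itself evens out the sides, 2911 and 2696. OGT, the enzyme that attaches O-linked N-acetylglucosamine to proteins, headed the first group at 3716 against a listed 0. It was followed by SPDYE2 at 3670, UCHL1, a neuronal-type deubiquitinase, at 3192 and DYNC1H1, the heavy chain of cytoplasmic dynein, at 2725. ADGRD1 stood at 2155 and CEP72 at 2038. All of these were listed at 0 in the glucose-deprived library. The same held for TNFAIP3, an inhibitor of NF-kB signalling, at 1483 and for BSG, a partner of lactate transporters, at 1311. At the opposite end, ACSL4, which activates long-chain polyunsaturated fatty acids and promotes ferroptosis, stood at 397 in the glucose-deprived library and was listed at 0 in the glutamine-deprived library. TPGS2 at 144, INTS6L at 137 and LINC01828 at 137 were likewise above 0 in the glucose-deprived library alone. So were PRMT3, an arginine methyltransferase acting on a ribosomal protein, at 116 and NARS2, the mitochondrial asparaginyl-tRNA synthetase, at 113. CARD18 stood at 113 there, BRAP at 104, RCN1 at 101 and ARFIP2 at 91.0. From ACSL4 to ARFIP2 each name rested on 1 transcript with a value, except TPGS2 with 2. A transcript at 0 in the glutamine-deprived library carried a value only where it was above 0 in the other. The listed 0 therefore does not show that these genes were absent from the glutamine-deprived library. ALKBH5 had 1 transcript with a value, listed at 0 in the glucose-deprived library and at 11.8 in the glutamine-deprived library.

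Among the 351 names above 0 in both libraries, which direction prevailed depended on the scaling. As deposited, 148 were at least 2-fold higher in the glutamine-deprived library and 89 at least 2-fold higher in the glucose-deprived library. With each library rescaled to 1000000 the numbers were 21 and 305. The median log2 ratio of these names was 0.61 as deposited; the median over all names, 4.32, is set by the names listed at 0 and by the pseudocount, and was 7.57 with a pseudocount of 0.1. HSPA5, the main chaperone of the endoplasmic reticulum, was at 357 in the glucose-deprived and 4192 in the glutamine-deprived library, a log2 ratio of 3.55 as deposited and of -0.84 after rescaling. EEF1A1, a translation elongation factor, was at 951 and 2100, a log2 ratio of 1.14 as deposited and of -3.25 after rescaling. For both names the largest transcript differed between the libraries. Names higher in the glutamine-deprived library under both scalings included XLOC_220679, MALAT1 and NEAT1, at log2 ratios of 5.97, 5.71 and 5.65 as deposited and of 1.58 and 1.31 after rescaling for the first pair. For this reason values in both libraries are given below without a direction for names whose ratio is smaller than the shift between scalings.

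XLOC_220679, a locus with no gene symbol in the files, was the most abundant name in both libraries. It took 5566 of the 42827 recovered reads (12.7 to 13.3%) in the glucose-deprived library and 38.8% of the reads (38.7 to 38.9%) in the glutamine-deprived library. MALAT1 took 2.42% (2.28 to 2.57%) and 6.01% (5.97 to 6.05%), and NEAT1 0.934% (0.847 to 1.03%) and 2.23% (2.21 to 2.25%). The ratio of MALAT1 to NEAT1 reads is one that no scaling alters, and it was chosen after the values were seen. It was 2.59 (95% counting interval 2.30 to 2.91) in the glucose-deprived and 2.69 (2.66 to 2.73) in the glutamine-deprived library. These intervals overlap. The ratio of XLOC_220679 to MALAT1 was 5.38 (5.03 to 5.75) and 6.45 (6.41 to 6.50). Next to XLOC_220679 and MALAT1, the glucose-deprived library was led by SNHG14 at 1134 (3107 in the glutamine-deprived library), EEF1A1, and NAMPT, the rate-limiting enzyme of NAD salvage, at 735 (1364). UBQLN1 followed at 584 (271), then NEAT1, CSNK2A2 at 475 (725), NORAD at 455 (797) and PTPN11 at 424 (362). In the glutamine-deprived library the names after XLOC_220679, MALAT1 and NEAT1 were HSPA5, OGT, SPDYE2, UCHL1, PDE10A at 3131 (159 in the glucose-deprived library) and SNHG14. Between the last pair stood IARS1, the cytosolic isoleucyl-tRNA synthetase, at 3113 (116). The 10 most abundant names held 25.1% (24.7 to 25.5%) of reads in the glucose-deprived library and 49.1% (49.1 to 49.2%) in the glutamine-deprived library. The 100 most abundant held 60.2% (59.7 to 60.6%) and 57.5% (57.4 to 57.6%). Only 393 names were above 0 in the glucose-deprived library against 9211 in the other. The top 100 are thus a far larger part of the names seen in the former, which by itself raises their share. Without XLOC_220679, a setting chosen after the data were seen, the shares were 14.8% and 17.3% for the top 10 and 54.5% and 30.7% for the top 100. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

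The 38 gene lists were fixed beforehand, with the median log2 ratio as the planned measure. Comparing how many of their names were listed above 0 with matched lists was added after the data were seen. Such counts of names do not show whether a pathway was active. Most listed members stood at 0 in the glucose-deprived library, so each list is described first by how many of its measured members were above 0 there, beside the number in 10000 random lists matched on the value in the glutamine-deprived library. In 3 of the 34 lists with a measured member that number lay above the central 95% of the matched lists, and in 0 it lay below, with no correction for the number of lists. A number below was possible only for the cytosolic ribosomal proteins and the long non-coding RNAs, since the interval of every other list began at 0. The 1st was the amino acid response, genes induced by ATF4 when amino acids run short, with 5 of 15 members above 0 and 1 (0 to 4) in matched lists. These were ASNS, which makes asparagine from aspartate with glutamine as nitrogen donor, at 188 in the glucose-deprived and 114 in the glutamine-deprived library, CBS at 180 and 333, and PHGDH, the first enzyme of serine synthesis, at 128 and 172. SLC3A2, a subunit of amino acid exchangers, stood at 109 and 630, and SLC1A4 at 27.8 and 83.8. DDIT4 at 984, MTHFD2 at 526 and SHMT2 at 168 were seen in the glutamine-deprived library and listed at 0 in the other. The next was the cytosolic ribosomal proteins, with 16 of 60 members above 0 and 5 (1 to 9) in matched lists. Among them were RPLP0 at 317 and 1626, RPL13A at 262 and 198, and RPL23A at 188 and 34.0, chosen after their values were seen. Others of the 16, also chosen so, rested on very few recovered reads in the glucose-deprived library. RPL8 and RPS3A had 2 reads each there, and RPL18, RPS20 and RPS29 had 1 each. Reads of pseudogenes cannot be told apart from those of these names. The last was the long non-coding RNAs, with 10 of 20 members above 0 and 3 (1 to 7) in matched lists. Besides MALAT1, NEAT1 and NORAD it included OIP5-AS1 at 368 and 672, CYTOR at 173 and 448 and GAS5, a host of small nucleolar RNAs, at 106 and 678, again chosen after their values were seen. KCNQ1OT1 stood at 967.5 and ZFAS1 at 510.1 in the glutamine-deprived library, and both were listed at 0 in the other.

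In the other measured lists the number above 0 in the glucose-deprived library lay within the central 95% of its matched lists. Of 18 measured glycolysis and glucose transport names, 2 were above 0 there, against 2 (0 to 5) in matched lists: SLC2A3, a glucose transporter, at 295 (547 in the glutamine-deprived library) and PKM, a pyruvate kinase, at 2.55 (1101). GPI stood at 416, PFKM at 405 and ENO1 at 437 in the glutamine-deprived library, and all 3 were listed at 0 in the other. Of 13 glutamine metabolism and transport names, GLUD1, glutamate dehydrogenase, was the 1 above 0, at 101 and 204, against 1 (0 to 3) in matched lists. SLC38A2, a glutamine transporter, stood at 0 and 161. Of 17 endoplasmic reticulum chaperone and unfolded protein response names, 4 were above 0, against 1 (0 to 4): HSPA5, HSP90B1 at 272 and 806, CANX at 176 and 149, and PDIA3 at 10.1 and 129. Of 19 aminoacyl-tRNA synthetases, IARS1 and GARS1 (104 and 534) were above 0 in both, against 2 (0 to 5). LARS1 stood at 983 and AARS1 at 808 in the glutamine-deprived library alone. None of the 11 measured m6A writers, erasers and readers was above 0 in the glucose-deprived library, against 1 (0 to 3) in matched lists. In the glutamine-deprived library IGF2BP3 stood at 376, HNRNPA2B1 at 349, HNRNPC at 124 and METTL3, the catalytic methyltransferase, at 101.

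The median log2 ratios of these lists were positive as deposited. They were 4.20 (95% order-statistic interval 1.56 to 7.40) for the amino acid response, 7.15 (3.93 to 8.30) for glycolysis and 5.95 (3.39 to 7.59) for glutamine metabolism. They were 4.88 (3.55 to 6.42) for the endoplasmic reticulum list, 5.13 (1.36 to 8.45) for the m6A list and 5.68 (1.37 to 7.77) for the long non-coding RNAs. Against the median of all names, 4.32, the amino acid response lay lower and the other 5 higher. Their percentiles among random lists matched on mean level were 39.0, 99.0, 56.1, 11.4, 44.9 and 77.8 in that order. Among random lists not matched on level the percentiles were 42.7, 100, 98.7, 82.8, 85.0 and 99.0. The ferroptosis and glutathione list had a median of 2.01 (-8.64 to 7.92), an interval that spans both directions, at percentile 1.07. Its members ACSL4, TFRC, the transferrin receptor, at 262 and 1054, and FTH1, the ferritin heavy chain, at 169 and 633, were above 0 in the glucose-deprived library, against 1 (0 to 3) in matched lists. Since most members were listed at 0 in the glucose-deprived library, these medians mainly carry the level in the glutamine-deprived library and the pseudocount. For a name at 0 there, the mean level is a fixed fraction of the log2 ratio. Matching on mean level therefore nearly sets the ratio being ranked, and the matched percentiles single out no list.

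Among the other lists, 4 of 18 ribosome biogenesis names were above 0 in the glucose-deprived library. They were NPM1 at 397 there and 720 in the glutamine-deprived library, NOP2 at 104 and 60.1, DKC1 at 26.6 and 79.1, and WDR12 at 16.5 and 15.8. For hypoxia-inducible factor targets it was 2 of 10, BNIP3 at 78.4 and 34.8 and ERO1A at 5.10 and 18.2. For mesenchymal and matrix names it was 2 of 10, FN1, fibronectin, at 344 and 963 and TGFBI at 138 and 331. Nuclear-encoded oxidative phosphorylation had 2 of 30, NDUFA4 at 98.6 and 1.56 and UQCRC2 at 89.8 and 60.0. MCL1, an apoptosis regulator, stood at 86.0 and 1217. A single member was above 0 in 13 lists, GLUD1 of glutamine metabolism among them. The others included GINS1 of DNA replication at 152 and 18.1, CENPF of mitosis at 144 and 52.2, NAPSA of the lung lineage at 161 and 18.9, and KRT8 of the epithelial list at 200 and 143. Further ones were HSPD1 of heat shock at 335 and 673, GLA of autophagy and lysosome at 147 and 644, and AEN of p53 targets at 116 and 190. CXCL8 of inflammatory cytokines stood at 5.08 and 40.3 and PPIA of the housekeeping list at 377 and 501. They also included FTH1 of NRF2 targets and PHGDH of serine and one-carbon metabolism. No member was above 0 in the glucose-deprived library in 9 lists. Among them were the 14 measured names of the tricarboxylic acid cycle, 13 of fatty acid oxidation, 12 of cholesterol synthesis and uptake, 8 of fatty acid synthesis and 7 of gluconeogenesis and the pentose phosphate pathway. In the glutamine-deprived library SREBF1, a transcription factor of lipid synthesis, stood at 964, ACADVL at 925 and TXNIP, a gene induced by glucose, at 161. Leukocyte markers and fibroblast and endothelial markers had rows but no member with a value, and mitochondrially encoded genes and replication-dependent histones had no row.

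Across all 9253 names, Pearson's r between the libraries on the log2 scale was 0.175 and Spearman's rho 0.133, and across the 351 names above 0 in both they were 0.353 and 0.341. Genes are not independent replicates, and these values describe the pair of libraries. The share of transcripts above 0 in the glucose-deprived library was 1.00% (0.783 to 1.28%) among those with 11 to 30 reads in the glutamine-deprived library, 5.68% (4.57 to 7.06%) among those with 101 to 300 and 18.7% (14.4 to 23.8%) among those with 301 to 1000. Where above 0, their median reads in the glucose-deprived library were 50, 77.5 and 100.5, with 66 for those at 0 glutamine-deprived reads, 17.5 for those at 1 to 3 and 380 for those at over 1000. Transcripts at 0 or 1 glutamine-deprived read were listed with a value only where above 0 in the glucose-deprived library.

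**Figure D2:**
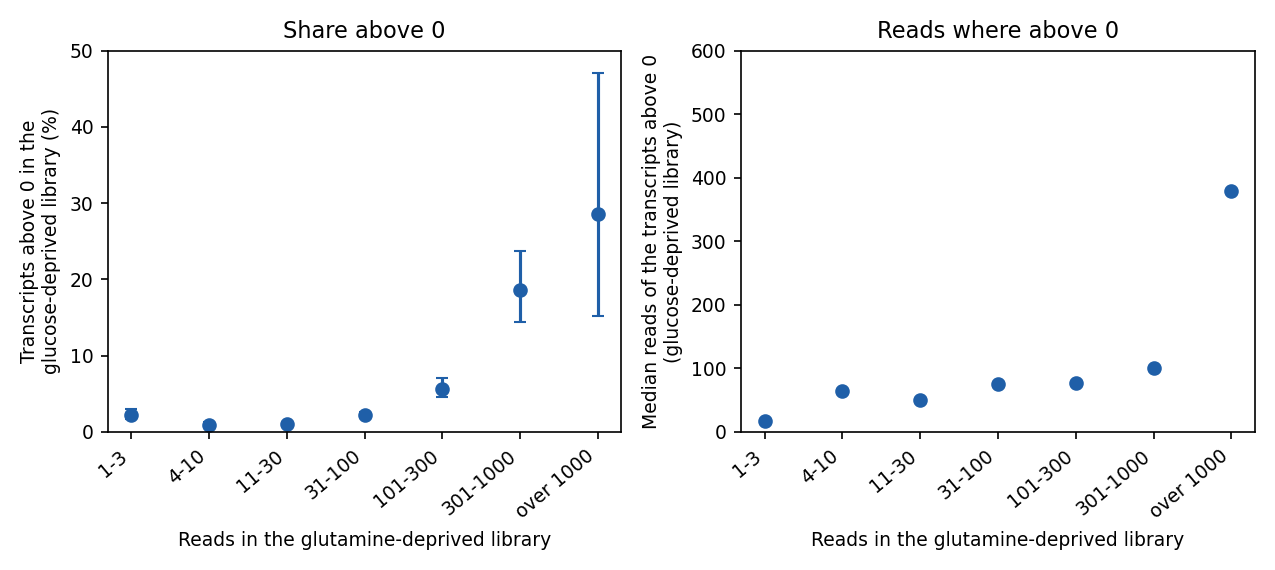
Transcripts are grouped on the horizontal axis by their reads in the glutamine-deprived library; the left panel gives the percentage above 0 in the glucose-deprived library with 95% Wilson intervals as bars, and the right panel the median reads of those above 0. The percentage is 18.7% at 301 to 1000 reads against 1.00% at 11 to 30, while the medians of these groups are 100.5 and 50 reads; the median is 17.5 at 1 to 3 reads and 380 above 1000.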

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

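Alternatives on names above 0 in both libraries, on single transcripts, without the locus XLOC_220679 and without the 3 most abundant names were chosen after the data were seen; the others were planned. As reported, 9139 names were at least 2-fold apart, 9008 higher in the glutamine-deprived and 131 higher in the glucose-deprived library. Without a minimum, with a minimum of 5, with a pseudocount of 0.1 and at 1.5-fold all 3 counts stayed within 1.5 times. Leaving out the minimum could change nothing, since every name passed it. A smaller pseudocount or a lower threshold can only add names, so these settings could not have lowered the counts. Rescaling to 1000000 left 347 higher in the glucose-deprived library (335 without the 3 most abundant names), and 4-fold left 85. Centring, which subtracts 4.32, gave 5607 apart, 2911 and 2696, or 51.9% against 98.6% higher in the glutamine-deprived library; centring fixes a nearly even split by its construction, and its centre is set by the zeros and the pseudocount. Counts changed by construction where fewer or more items entered: 5578, 5503 and 75 for protein-coding symbols, 18551, 18302 and 249 for transcripts, 233, 148 and 85 for a minimum of 1 in both libraries, and 237 and 148 for names above 0 in both. Pearson's r became 0.130 with a pseudocount of 0.1, and r and rho became 0.353 and 0.341 on names above 0 in both. Without XLOC_220679 the 10 and 100 most abundant names held 14.8% and 54.5% in the glucose-deprived and 17.3% and 30.7% in the glutamine-deprived library. Setting aside mitochondrially encoded and small RNA names moved no share and could move none. The only such name with a value was TERC, at 3 reads in the glutamine-deprived library.

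Against random lists not matched on level, 10 of 30 lists changed their side of the middle percentile, the endoplasmic reticulum list from 11.4 to 82.8 and the m6A list from 44.9 to 85.0 among them. List medians depended on the treatment of the zeros and, for the long non-coding RNAs, on rescaling. For the amino acid response the median was -0.12 when centred, 7.45 with a pseudocount of 0.1 and 0.89 among names in both libraries by either rule. The endoplasmic reticulum list gave 0.56, 8.16 and 2.55, and glutamine metabolism 1.63, 9.25 and 1.01. Glycolysis gave 2.83 centred and 9.71 with the smaller pseudocount, the m6A list 0.81 and the long non-coding RNAs 1.36 centred; the latter, at 5.68 as deposited, gave 2.37 after rescaling and 1.72 among names in both libraries. Centring also turned hypoxia-inducible factor targets to -0.93, cholesterol synthesis to -0.65, mitosis to -1.17, heat shock to -1.61, mesenchymal to -0.47, epithelial to -0.93, apoptosis to -0.43 and ferroptosis to -2.31. Among names in both libraries by either rule, oxidative phosphorylation was at -2.93 and DNA replication at -3.00, resting on 2 names and 1 name, mitosis at -1.45 and epithelial at -0.48, on 1 each.

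Single names turned with the scaling. After rescaling, after centring and after rescaling without the 3 most abundant names, log2 ratios were -2.94, -2.87 and -2.28 for SNHG14, -3.25, -3.18 and -2.59 for EEF1A1 and -0.84, -0.77 and -0.18 for HSPA5; PDE10A was at -0.10 and -0.031 under the first and the next and at 0.56, not turned, under the last. NAMPT, NORAD and CSNK2A2, under 2-fold apart as deposited at 0.89, 0.81 and 0.61, were at -3.50, -3.59 and -3.79 after rescaling and below 0 under the other 2. These shifts are arithmetic, since each setting moved all of these names by nearly the same amount. They do not show which scaling is right. No paired analysis was possible because each condition had 1 library, and no library could be left out. Alternatives meant for counts, for an immunoprecipitate over input and for peak lists were not run, since the values were neither. The number of reads, 42827 in the glucose-deprived library, widens its counting intervals and is not by itself what leaves most names at 0, as thinning showed.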

Other observations

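The tests of read depth, of amplified molecules, of transcript levels, of a chance draw of molecules and of shared reads at equal level were chosen after the results were seen; the first comparison of shared reads and those of transcripts per name were chosen before.

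In some names the libraries drew on different transcripts. The largest EEF1A1 transcript of the glucose-deprived library stood at 925 there and at 0.77 in the glutamine-deprived library, while the largest of the glutamine-deprived library stood at 818 there and at 0 in the other. For HSPA5 the values were 349 and 4.73 for the former and 2675 and 0 for the latter. By gene class, names of protein-coding genes held 64.9% of reads in the glucose-deprived and 41.2% in the glutamine-deprived library, long non-coding RNA names 12.4% and 13.5%, and unnamed loci 15.0% and 40.2%. Without XLOC_220679, a setting chosen after the data were seen, these shares were 74.6% and 67.3%, 14.2% and 22.1%, and 2.32% and 2.28%.

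Few transcripts were above 0 in the glucose-deprived library, 474 of the 18663 with a value. Fewer reads alone do not account for this: thinning the glutamine-deprived reads to 42827 left at least 8257 transcripts above 0 in each of 1000 draws, with a median of at most 2 reads against 69 observed outside the 3 most abundant names. Few RNA molecules amplified many times stay open: the median reads of transcripts at 301 to 1000 glutamine-deprived reads were 1.55 times those at 4 to 10, little for such a step in level, but 5.74 times those at 1 to 3, while transcripts at 0 had a median of 66. Different transcript levels in glucose-deprived cells cannot be told apart from this, because condition and library are the same 1 sample. Nor can a difference in library type, since the labels do not say whether either library is an immunoprecipitate or an input. The rho of 0.324 across 348 names lay below thinned reads (0.783 to 0.807) but within draws of 958 molecules (0.303 to 0.456), a number set so that the draws give 474 transcripts; such draws expected 136 transcripts at 101 to 300 reads where 76 were seen, and selection by the authors' processing was not tested.

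Of the 474 transcripts, 143 had 3 or fewer reads in the glutamine-deprived library, 99 of them none and 23 of them 1 read, and at 0 or 1 read a transcript was listed only where it was above 0 in the glucose-deprived library. For the 21 at 2 or 3 reads a chance draw of 958 molecules from the glutamine-deprived pool does not give as many: the highest of 1000 draws held 11. The share of transcripts at 2 or 3 reads that were above 0, 1.07% (0.700 to 1.63%), was close to the 1.00% (0.783 to 1.28%) at 11 to 30 reads, where a draw would follow level. The draw was sized to give all 474 transcripts, though it cannot yield the 99 at 0 reads. It also expected 147 transcripts at 31 to 100 reads where 92 were seen, so the comparison speaks only to this draw. Reads of a gene shared among its transcripts stay open. Another transcript of the same name with over 10 glutamine-deprived reads was listed for 53.1% of the 143 and 62.0% of 1945 transcripts at 0 in the glucose-deprived library, a comparison that settles nothing because the latter all had 2 or 3 reads. At 2 or 3 reads in both sets the difference was 9.47 percentage points (Newcombe interval -12.02 to 24.4), and a difference in RNA between the conditions was not tested apart from the library.

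In 3 lists names were above 0 in the glucose-deprived library more often than names of like level. Random lists were also matched on level and on the number of transcripts. For the ribosomal proteins the central 95% then reached 8 against 16 observed names, some of them at 1 or 2 reads, so more transcripts per name did not account for that list. For the long non-coding RNAs it reached 8 against 10 observed. The match placed all names with many transcripts in 1 group, GAS5 with 53 and PVT1 with 33 among them, and cannot decide for this list. For the amino acid response it reached 4 against 5 observed, a margin of 1 name that cannot decide either. No test here separated an effect of glucose deprivation from a difference in library type, or from reads of paralogs, pseudogenes or the abundant messenger RNA of the same gene.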
